A study of Mus musculus with 4 samples.

How the data were processed

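Gene expression was measured by RNA sequencing in 4 libraries from mouse skin, 2 in each of 2 groups. Per the labels, the cells came from pre-tumorigenic dermal hyperplasia, in which tamoxifen had switched on the red fluorescent protein tdTomato in cells with an active tyrosinase (Tyr) promoter, and the tdTomato-positive cells were collected by fluorescence-activated sorting. All mice carried oncogenic NrasQ61K under the Tyr promoter. The group named Ezh2Y646N also carried a conditional allele of the histone methyltransferase mutant Ezh2Y646N in the ColA1 locus. RNA was prepared with a micro-scale column kit, and libraries were made with a stranded total RNA kit for very small inputs that removes ribosomal RNA, per the labels' protocols. The labels number the libraries of each group 1 and 2 and do not say whether these came from separate animals. Y-linked RNA was present in 1 library labelled Ezh2Y646N and near 0 in the other, so these were not repeats of the same material, but nothing settles this for the NrasQ61K group. P-values measure the spread between these libraries, which in that group may be technical.

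The deposited values are read counts per Ensembl gene, whole numbers with no normalization, with 22524 genes per library. The submitters' processing notes name bcl2fastq 2.19, Trimmomatic, STAR 2.5.4b, featureCounts, edgeR and the mouse build GRCm38, without roles or order. The annotation release, the strand setting of the counting and any filter on genes are not given in the sources used here. Reads from overlapping or antisense genes, and from near-identical copies such as members of the Skint, Serpinb3, keratin and Krtap families, may therefore have been divided between genes or lost, and values of such genes are uncertain. Gene symbols, biotypes and positions were taken from GENCODE M21 on GRCm38, in which 22291 gene identifiers were found and 233 were not. Coordinates are 1-based.

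Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default minimum of 10 counts and of 15 counts over all libraries, libraries were scaled by the trimmed mean of M-values (TMM), and a quasi-likelihood model with group as its term was fitted with robust dispersion estimates and 2 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Fold changes are log2 of Ezh2Y646N over NrasQ61K. Their standard error (SE) was computed from the fold change and the F statistic. Expression levels are given as CPM, counts scaled by the TMM-adjusted library sizes. The replicate number was not used as a block.

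Before the data were examined, 33 gene lists were fixed. The biology lists covered intraflagellar transport, the BBSome and transition zone, centrioles and basal bodies, the union of these as the primary cilium, motile cilia, Hedgehog signalling, Wnt/beta-catenin targets, pigmentation, neural crest and invasive melanoma genes, adherens junctions and adhesion, Polycomb complexes, Hox genes, developmental transcription factors that are Polycomb targets, tumour suppressors and inhibitors of cell cycle kinases, proliferation, MAPK output, antigen presentation, interferon response and oxidative phosphorylation. The others covered cell types that a sort from skin could hold (keratinocytes and hair follicle, fibroblasts, endothelium, pericytes and smooth muscle, macrophages and dendritic cells, lymphocytes and mast cells, Schwann cells and glia, adipocytes, skeletal muscle, erythroid cells) and signs of RNA quality or sex (ribosomal proteins, mitochondrially encoded genes, dissociation stress, sex-linked genes). Of the 899 distinct genes, 891 were found by symbol, 3 under another symbol, and 5 had no row. The 30 lists with 5 or more tested members were compared with all other genes by limma 3.58.1's camera, 2-sided, with a preset correlation between genes of 0.01, and the p-values were adjusted over these lists. Camera with an estimated correlation and the rotation test fry were run beside it. Camera's p-values with an estimated correlation do not isolate the effect of correlation between genes, as described with the alternatives below. Counts of members past the threshold are given over all genes tested and, where stated, adjusted over the list alone.

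The genes to be named were also fixed before the data were examined. They are Ezh2, Nras and Tyr, the 10 genes per direction with the smallest p among those past the threshold with no overlap between groups (predicted genes and pseudogenes excepted), up to 3 members with the smallest p from each biology list other than the primary cilium union, and the 2 members of highest mean CPM from each other list. The rule gave 105 genes. Another 23 genes were chosen after their values were seen and are marked as such. Of all these, 2 genes are not reported here, though they remain in the lists and counts.

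Total counts per library ranged from 14808801 to 20600297. For medians given with a floor, a gene at 0 counts in both libraries of a group was set to 3 counts per library. This equals 0.172 and 0.207 CPM in Ezh2Y646N replicates 1 and 2 and 0.190 and 0.144 CPM in NrasQ61K replicates 1 and 2. In all tests, fold changes and CPM, counts of 0 were left as they were. Intervals of shares are 95% Wilson intervals. Intervals and floors cover counting error only. The procedure was tested on simulated data for 14265 genes with the means and library sizes of these libraries. It recovered 16% of 50 genes changed 2-fold, 84% of 50 changed 4-fold, 100% of 50 changed 8-fold and 98% of 50 changed 16-fold. Of 166 calls, 7.23% were genes simulated as unchanged, and camera called 0 of 29 unchanged lists and the 1 shifted list. The genes were simulated as independent of each other and the lists drawn at random. The simulation therefore does not measure camera's false calls for lists of correlated genes, such as the cell type lists.

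Alternatives fixed beforehand were other scalings (RLE size factors, upper quartile, library totals only), no filter on low counts, a filter of 50 counts in 2 libraries, DESeq2 1.42.0, limma voom, no robust estimation, mitochondrial, haemoglobin and small RNA genes left out, the replicate number as a block, each library left out in turn, a threshold of 0.10, and a minimum of 2-fold. After the data were seen, 2 alternatives were added, leaving out keratin genes with the epidermal differentiation complex and leaving out Y chromosome genes. The 6 gene classes of keratins and epidermal markers were also drawn up after the data were seen, and 1 of them, the suprabasal markers, was written with the called genes in view. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.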

Results

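Expression was measured in tdTomato-positive cells sorted from pre-tumorigenic dermal hyperplasia of NrasQ61K mice, with 2 libraries from mice that also carried the Ezh2Y646N allele and 2 from mice that did not. Ezh2 is the catalytic subunit of Polycomb repressive complex 2, and the series title links it to loss of the primary cilium in melanoma. The question put to these libraries is which genes differ between NrasQ61K cells with and without the mutant Ezh2. Total counts were 18115390 and 15083133 in the libraries labelled Ezh2Y646N and 14808801 and 20600297 in those labelled NrasQ61K. Pearson's r of log2 CPM with 1 added, computed across genes, which are not independent replicates, was 0.974 between the libraries labelled Ezh2Y646N, 0.964 between those labelled NrasQ61K, and 0.928 to 0.959 between groups. Replicates differed by more than counting noise, with a chi-square per degree of freedom of 42.1 and 92.3, and the biological coefficient of variation was 27.9%.

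Ezh2 (ENSMUSG00000029687, GRCm38 chromosome 6, 47530139 to 47595341) was measured at 135 and 91.6 CPM in the libraries labelled Ezh2Y646N and at 171 and 75.1 CPM in those labelled NrasQ61K. The means were 113 ± 30.9 and 123 ± 67.6 CPM (SD, n = 2 each). The log2 fold change was -0.12 with an SE of 0.39, and edgeR's adjusted p was 0.944, so no difference in Ezh2 RNA was detected. Without NrasQ61K replicate 1 the log2 fold change was 0.59, and without Ezh2Y646N replicate 2 it was 0.13. Counts per gene do not tell the mutant transcript from the endogenous one, so the labels could not be checked by this gene, and the groups are called by their labels throughout. The Nras gene (chromosome 3, 103058285 to 103067914) had a log2 fold change of -0.07 (SE 0.23, edgeR's adjusted p = 0.944). Both groups carried NrasQ61K under the Tyr promoter, and counts per gene do not tell its RNA from that of the endogenous gene. Tyr (chromosome 7, 87424771 to 87493512), which encodes tyrosinase and whose promoter drives the labelling, was at 240 ± 28.1 and 177 ± 6.88 CPM (SD, n = 2 each), a log2 fold change of 0.44 (SE 0.22, adjusted p = 0.435).

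**Figure D1:**
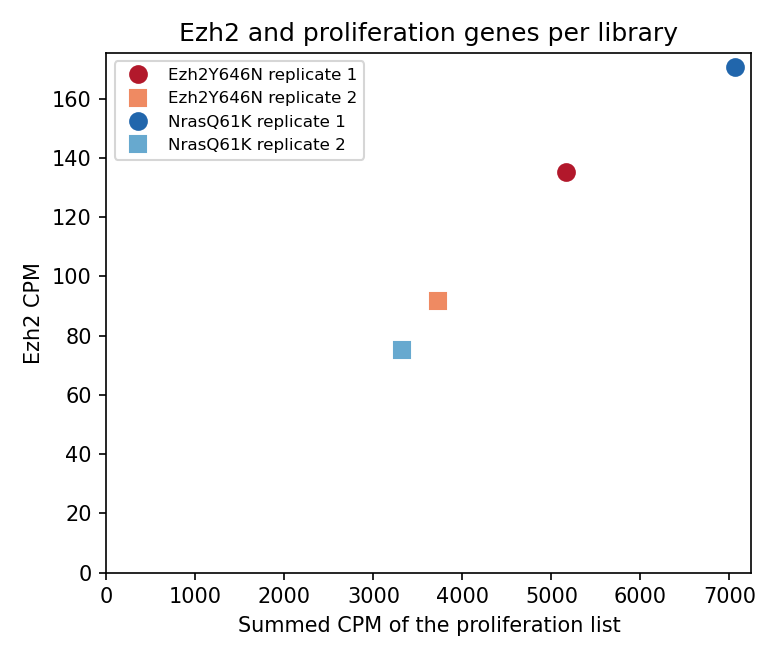
Ezh2 CPM against the summed CPM of the proliferation list, one point per library, both axes from 0, red and orange for Ezh2Y646N and blue for NrasQ61K. The library with the most Ezh2 (NrasQ61K replicate 1, 171 CPM) had 7060 CPM of proliferation genes, and the one with the least (NrasQ61K replicate 2, 75.1 CPM) had 3319.

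Hrnr, Alox12b and Sdr9c7, which act in the skin barrier, were among the 10 genes with the smallest p that were higher in the libraries labelled Ezh2Y646N, and Cmah and Rspo4 led those that were lower. Hrnr, which encodes the cornified envelope protein hornerin, was at 237 ± 115 CPM against 8.60 ± 5.47 (SD, n = 2 each), a log2 fold change of 4.77 with an SE of 0.55. Alox12b and Sdr9c7, enzymes of the skin's lipid barrier, had log2 fold changes of 3.78 (SE 0.40) and 3.57 (SE 0.36). The other 7 genes named for the higher direction were Serpinb3b (3.33), Homer2 (2.85), Mme (2.73), Skint6 (2.56), Synpo2 (2.55), Npr3 (2.53) and Rab11fip4 (1.997). Skint6 and Serpinb3b belong to families of close copies, and their counts are uncertain. In the lower direction, Rspo4, a secreted enhancer of Wnt signalling, had a log2 fold change of -4.70 (SE 0.45), from 16.6 ± 4.56 CPM in the libraries labelled NrasQ61K to 0.633 ± 0.0819 (SD, n = 2 each). Cmah, which encodes a sialic acid hydroxylase, had one of -4.20 (SE 0.35). The other 8 were Gdf10 (-4.08), F5 (-3.99), Pappa2 (-3.98), Corin (-3.75), Lrat (-3.70), Pthlh (-3.48), Mgat4a (-2.42) and Pdlim7 (-2.06). The adjusted p in edgeR's quasi-likelihood test was 0.022 for each of these 20 genes. Hrnr lost its call with the replicate number as a block, a pairing that the labels do not give.

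In all, 14265 genes were tested, of which 157 were higher and 96 lower in the libraries labelled Ezh2Y646N at an adjusted p under 0.05, and 2039 had an unadjusted p under 0.05. The median size of the called changes was 2.33 on the log2 scale, and 161 of the 253 calls were at least 4-fold. The groups did not overlap in 44.2% of the tested genes, where chance gives 33.3%. These counts depend on single libraries: without Ezh2Y646N replicate 1 they were 49 higher and 43 lower, without Ezh2Y646N replicate 2 168 and 51, without NrasQ61K replicate 1 219 and 221, and without NrasQ61K replicate 2 730 and 393. DESeq2 called 505 and 378.

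**Figure D2:**
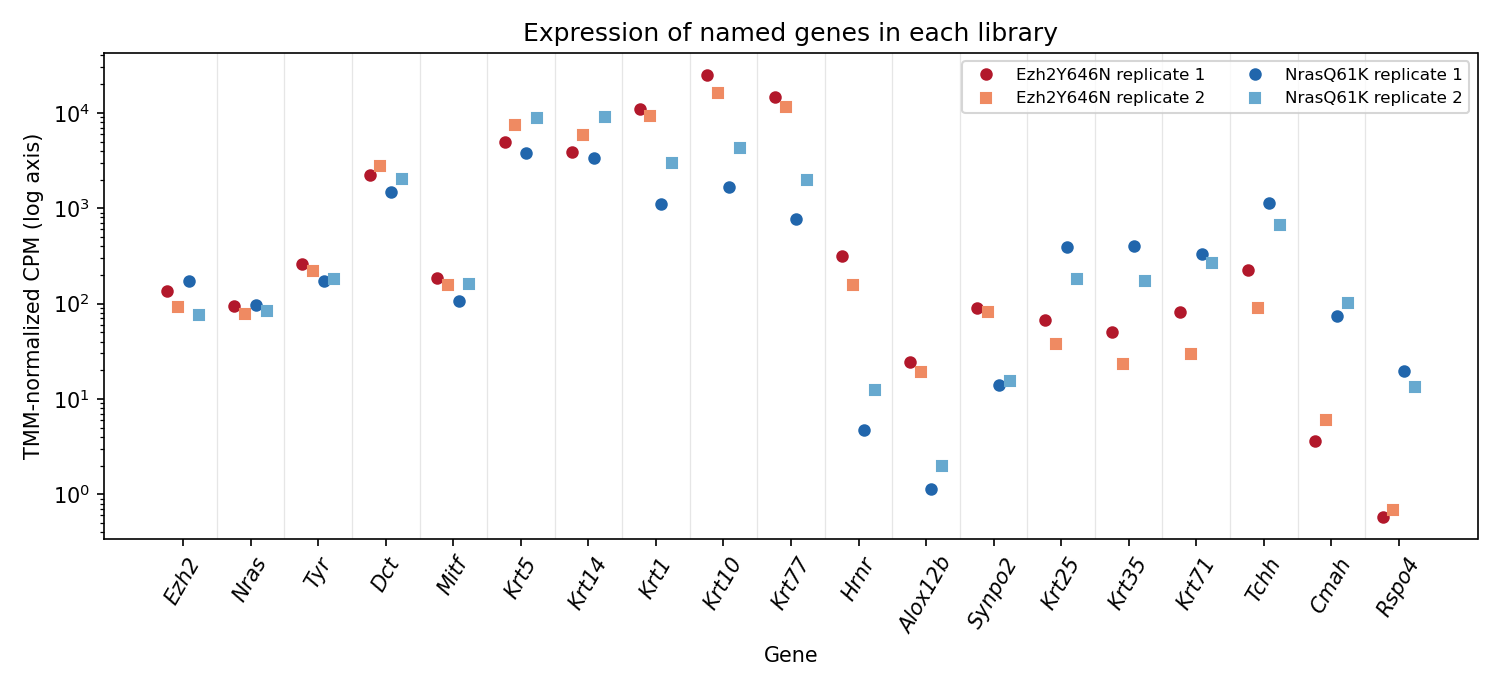
TMM-normalized CPM (log axis) of 19 genes, one point per library, red and orange for Ezh2Y646N and blue for NrasQ61K. Hrnr lies at 319 and 156 CPM against 4.74 and 12.5, while Krt25 lies at 66.7 and 37.4 against 390 and 180, and Ezh2, Nras and Mitf overlap between groups; some of the genes were chosen after their values were seen.

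No primary cilium gene passed the threshold. Of 114 tested members, 37 had a log2 fold change above 0 and 77 below, with a median of -0.17 and a median SE of 0.30. The test in edgeR called 0 of them, as did DESeq2 and limma voom, and 1 had an unadjusted p under 0.05. This was Ift20, a subunit of the intraflagellar transport machinery, at 69.4 ± 8.31 against 40.8 ± 4.20 CPM (SD, n = 2 each), a log2 fold change of 0.77 (adjusted p = 0.163). Camera's adjusted p for the list was 0.30, and 0.986 with an estimated correlation. The median was 0.04 without NrasQ61K replicate 1, and -0.25 without NrasQ61K replicate 2, where camera's adjusted p was 0.0141. In simulated data of this design 16% of 2-fold changes were recovered, so changes of that size in single cilium genes were mostly not detectable. Keratin genes took 1.70% to 6.42% of counts per library and the pigmentation list 0.588% to 0.624%. The share of RNA from melanocytes was not measured, so a change confined to them, in this list or those below, could be diluted.

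None of the 3 parts of the cilium list was called by camera with all 4 libraries. Intraflagellar transport had a median of -0.01 over 33 genes (camera's adjusted p = 0.985), with Wdr19 at -0.59 and Ift57 at -0.42. The BBSome and transition zone list had a median of -0.21 over 43 genes (adjusted p = 0.32), with Tctn3 at -0.81, Bbs1 at -0.80 and Mkks at -0.53. Centriole and basal body genes had a median of -0.24 over 38 genes (adjusted p = 0.30), with Cep135 at -0.74, Kif24 at -0.72 and Cep63 at 0.48; without NrasQ61K replicate 2 the list was lower (0.00223). Of 19 motile cilium genes 0 passed in edgeR, DESeq2 and voom, and 3 had an unadjusted p under 0.05, the dynein heavy chains Dnah11 (-3.08) and Dnah1 (1.68) and Drc1 (2.70). Camera's adjusted p for that list was 0.801. The rotation test fry gave it 0.781 for a change in one direction and 0.0286 for change in either direction. The Hedgehog and Wnt lists were also not called with all 4 libraries and the main filter. Of 19 Hedgehog genes 0 passed in edgeR and voom, DESeq2 called 1 lower, and 2 had an unadjusted p under 0.05, Gli3 (-1.55) and Gas1 (-1.27), with Sufu at -0.45; camera's adjusted p was 0.30. Of 23 Wnt/beta-catenin targets 0 passed over all genes tested, 3 were lower adjusted over the list alone, 6 had an unadjusted p under 0.05, and DESeq2 called 4 lower. Their lowest p-values belonged to Wif1 (-1.86, adjusted p = 0.0507), Bambi (-2.28, 0.0586) and Notum (-2.13, 0.0586), and camera's adjusted p was 0.145. The Wnt list was lower without NrasQ61K replicate 2 (0.00112) and with no filter on low counts (0.0295).

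Pigmentation genes did not separate the groups. Of 32 tested members 0 passed in edgeR and voom, 3 had an unadjusted p under 0.05, and DESeq2 called 1 lower. The median log2 fold change was 0.23 and camera's adjusted p 0.337. Gpnmb, a melanosomal glycoprotein, had a log2 fold change of -1.18, the organelle motor Myo5a -0.71 and Ptgds 0.63. Chosen after their values were seen, the melanin enzyme gene Dct was at 2480 ± 391 and 1744 ± 365 CPM (SD, n = 2 each), the lineage regulator Mitf had a log2 fold change of 0.35 and Sox10 one of 0.16, none past the threshold. The list took 0.607% and 0.599% of counts in the libraries labelled Ezh2Y646N and 0.588% and 0.624% in those labelled NrasQ61K, with 95% Wilson intervals of 0.603 to 0.610, 0.595 to 0.603, 0.584 to 0.592 and 0.620 to 0.627.

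Neural crest and invasive genes were lower as a list, with a median of -0.60 over 30 genes and a camera adjusted p of 1e-05; the adjusted p was 0.592 with an estimated correlation. The 3 members past edgeR's threshold fell: the matrix genes Fn1 (-1.40, SE 0.22, adjusted p = 0.0343) and Tnc (-1.90, SE 0.34, 0.0424), and Pdgfrb (-1.58, SE 0.30, 0.0499), a receptor of mesenchymal cells. Adjusted over the list alone, 6 members were lower, and 4 of the list's genes are also in other lists. Pdgfrb lost its call with RLE size factors, in voom, with mitochondrial, haemoglobin and small RNA genes left out, and without any 1 of Ezh2Y646N replicate 1, Ezh2Y646N replicate 2 and NrasQ61K replicate 1, Fn1 without either Ezh2Y646N library, and Tnc without Ezh2Y646N replicate 1. Fibroblast markers moved the same way, with a median of -1.13 over 20 genes (camera's adjusted p = 2.65e-08, and 0.592 with an estimated correlation). Of these 2 fell, named after their values were seen, Dpt (-2.08) and Cd34 (-1.53), and the abundant collagens Col1a1 and Col3a1 had log2 fold changes of -1.13 and -1.20 without passing. Dpt lost its call in voom and without any 1 of Ezh2Y646N replicate 1, Ezh2Y646N replicate 2 and NrasQ61K replicate 1, and Cd34 with RLE size factors, in voom and without either Ezh2Y646N library.

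Developmental transcription factors that are Polycomb targets were lower as a list, with a median of -0.47 over 37 genes and a camera adjusted p of 0.000434; the adjusted p was 0.592 with an estimated correlation. The homeobox genes Barx2 (-2.01, SE 0.32, adjusted p = 0.0343) and Alx4 (-2.87, SE 0.52, 0.0442) fell, and Msx1 had a log2 fold change of -3.14 without passing (0.0525). Adjusted over the list alone, 2 members were higher and 9 lower. Markers of some other cell types were lower in the same libraries, with medians of -1.13 for fibroblasts, -0.80 for endothelium and -3.14 for the keratins of the hair shaft and inner root sheath, a class drawn up after the data were seen. Other markers were higher, with medians of 0.75 for Schwann cells and glia, 1.55 for erythroid cells and 0.60 for skeletal muscle. The suprabasal epidermis markers, also drawn up after the data were seen, had a median of 2.11. Homeobox genes such as Msx1 and Alx4 are also expressed in hair follicles or dermal cells. Barx2 lost its call without either Ezh2Y646N library and Alx4 in voom and without Ezh2Y646N replicate 2. Of 34 genes of the Polycomb complexes 0 passed in edgeR, DESeq2 and voom, and 2 had an unadjusted p under 0.05; the median was -0.04 and camera's adjusted p 0.847. The named members were Phf19 (1.66), Phc1 (-0.90) and Cbx7 (0.68). Of 29 Hox genes 0 passed in edgeR and voom, 4 had an unadjusted p under 0.05, and DESeq2 called 1 higher and 1 lower. Their median was -0.22 (camera's adjusted p = 0.296), with Hoxa7 at 1.28, Hoxc13 at -1.42 and Hoxb6 at -0.94.

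Lists of growth and signalling gave no call in edgeR or voom over all genes tested. Proliferation genes had a median of -0.26 over 55 members (camera's adjusted p = 0.30), 1 member with an unadjusted p under 0.05 and 0 called by DESeq2; Gins2, Ttk and Cdc20 had log2 fold changes of 0.81, 0.90 and -0.48. The list was lower without NrasQ61K replicate 2 (camera's adjusted p = 4.55e-08) and without Ezh2Y646N replicate 1 (0.0045), and higher without NrasQ61K replicate 1 (8.67e-05). MAPK output genes had a median of -0.17 over 21 members (adjusted p = 0.358, and in fry 0.391 for one direction and 0.0221 for either), 5 with an unadjusted p under 0.05 and 0 called by DESeq2, with Epha2 at -0.84, Dusp6 at -0.75 and Spry1 at 0.59. Tumour suppressors and cell cycle inhibitors had a median of -0.16 over 26 members (adjusted p = 0.296), 3 with an unadjusted p under 0.05 and 1 called lower by DESeq2, with Igfbp7 at -1.01, Rassf1 at -0.85 and Cdkn1a at 0.65. Adhesion genes had a median of 0.05 over 28 members (adjusted p = 0.753), 6 with an unadjusted p under 0.05 and 2 called higher by DESeq2. Ncam1 (1.10, adjusted p = 0.0507) was past the threshold when adjusted over the list alone, and Cdh4 and Cdh11 were at 1.45 and -1.13.

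**Figure D3:**
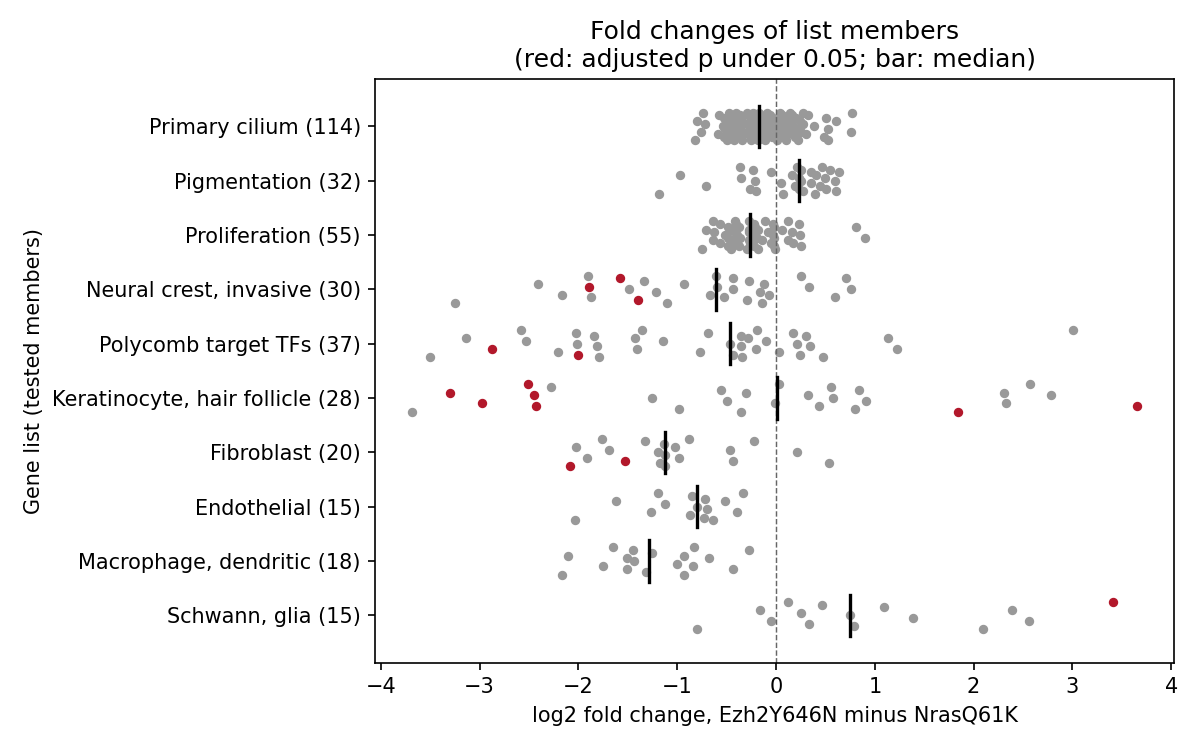
Log2 fold change, Ezh2Y646N minus NrasQ61K, of each tested member of 10 gene lists, one point per gene, red where edgeR's adjusted p was under 0.05, with a bar at each list's median. The medians run from -1.28 for macrophage and dendritic cell genes to 0.75 for Schwann cell and glia genes, and the keratinocyte list has called members on both sides of 0.

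Keratinocyte and hair follicle markers, a list for another cell type that the sort could hold, moved in both directions. Of 28 tested members 2 rose and 5 fell, with a median of 0.01 and a camera adjusted p of 0.985. The list was lower without NrasQ61K replicate 1 (0.0164). The members that rose were Lor (3.66) and Ivl (1.84), proteins of the cornified envelope. Those that fell were Krt6a (-3.30), Krt35 (-2.98), Tchh (-2.51), Krt25 (-2.45) and Krt71 (-2.43), of which all but Krt6a belong to the hair shaft or its inner root sheath. These 7 genes were named after their values were seen. The list's most abundant members were Krt10, at 20460 ± 6239 against 2980 ± 1880 CPM (SD, n = 2 each; adjusted p = 0.0514), and Dsp, at 15800 ± 112 against 9093 ± 3766 (adjusted p = 0.448). Ivl and Krt6a lost their calls without Ezh2Y646N replicate 1; Krt6a also without Ezh2Y646N replicate 2; Krt35 and Krt25 without either Ezh2Y646N library; Tchh and Krt71 with RLE size factors, without Ezh2Y646N replicate 2 and without either NrasQ61K library; and Tchh also with a fit that was not robust and with mitochondrial, haemoglobin and small RNA genes left out.

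Of the 30 lists tested, camera called 1 higher and 5 lower, while fry's test for change in one direction called 0. Its adjusted p was 0.391 for neural crest and invasive genes, 0.386 for Polycomb targets, 0.391 for fibroblasts, 0.393 for endothelium, 0.518 for macrophages and dendritic cells and 0.657 for Schwann cells and glia. For change in either direction fry called 3, which were neural crest and invasive genes (0.0114), MAPK output and motile cilium. Besides fibroblasts, markers of 3 other cell types were called as lists by camera. Endothelial genes were below 0 in 15 of 15 members, with a median of -0.80 and a camera adjusted p of 1.01e-05 (adjusted p = 0.975 with an estimated correlation). In that list 0 members passed in edgeR and voom, 6 had an unadjusted p under 0.05, and DESeq2 called 2 lower; Plvap and Pecam1 were at -1.20 and -0.87. Macrophage and dendritic cell genes were below 0 in 18 of 18 members, with a median of -1.28 and a camera adjusted p of 2.78e-06 (adjusted p = 0.975 with an estimated correlation). Again 0 passed in edgeR and voom, 10 had an unadjusted p under 0.05, and DESeq2 called 4 lower; Lyz2 and Ctss were at -1.51 and -1.65. Schwann cell and glia genes were higher, with a median of 0.75 over 15 members and a camera adjusted p of 0.000645 (adjusted p = 0.975 with an estimated correlation). In that list 1 member was higher in edgeR, 0 passed in voom and DESeq2 called 4 higher. An unadjusted p under 0.05 was found in 7 members, of which 1 was lower. Of the named members, Mbp was at 2.39 and Egr2 at -0.80 without passing. Of the list's genes 7 are also in other lists, which include pigmentation. The camera call ended without Ezh2Y646N replicate 1 (adjusted p = 0.0896) and without NrasQ61K replicate 1 (0.451). Of 10 pericyte and smooth muscle genes 1 fell, Acta2 (-1.75), named after its value was seen, which lost its call without either Ezh2Y646N library; the list had a median of 0.07, a mean of -0.15 and a camera adjusted p of 0.419, with Cspg4 and Notch3 at 0.31 and 0.06.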

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

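The alternatives without keratin and epidermal differentiation complex genes and without Y chromosome genes were chosen after seeing the data, the others before. With 2 libraries per group, only large changes were within reach, and a left-out library leaves a lone one that is assumed to vary like the other group. In 16 refits none of the 253 called genes still tested changed sign, and the 20 genes named for the smallest p-values kept their calls without each library in turn. These 20 were picked from the same 4 libraries for small p and no overlap between groups, so their calls were likely to be kept. Of the 157 higher calls, 41 were kept without Ezh2Y646N replicate 1, 113 without Ezh2Y646N replicate 2, 146 without NrasQ61K replicate 1 and 156 without NrasQ61K replicate 2; of the 96 lower calls 25, 40, 82 and 89 were. Leaving out 1 library, the higher calls ranged from 49 to 730, the lower calls from 43 to 393, the lists higher from 1 to 3 and the lists lower from 6 to 9, the median of the primary cilium list from -0.254 to 0.042 and the log2 fold change of Ezh2 from -0.55 to 0.59. The cause was not tested.

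Other settings changed counts of calls. With library totals only, which moved the median of all genes by -0.115 on the log2 scale, 153 genes were lower. Higher and lower calls were 686 and 616 with no filter on low counts, 505 and 378 with DESeq2, and 322 and 245 at a threshold of 0.10. All of the main calls were among those of DESeq2 and of the fit with no filter. With keratin and epidermal differentiation complex genes left out, 2 lists were higher, the added one being keratinocytes and hair follicle (camera's adjusted p = 0.0308). That list then lacked its 5 members that fell, Krt6a, Krt35, Tchh, Krt25 and Krt71, and its 2 that rose, Lor and Ivl. It was therefore a different list from the one tested with all genes. With an estimated correlation between genes, 0 lists were higher and 0 lower. This does not show that correlation between genes removed the calls. For Polycomb targets the estimated correlation was -0.021, below the preset 0.01, yet camera's unadjusted p rose from 7.23e-05 to 0.0437. The cause was not tested. The replicate numbers pair no samples by the labels, and same-numbered libraries deviated from their group means with a correlation across genes of 0.141; with the replicate block, 710 genes were higher and 627 lower, on 1 residual degree of freedom, and Hrnr lost its call.

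Of 2007 values of the 127 named genes other than Ezh2, 1785 kept their direction and side of the threshold, 47 lost the call, 141 gained one and 34 reversed, all 34 in genes not called. Fos reversed with RLE size factors (0.016), DESeq2 (0.015), voom (0.075) and the replicate block (0.065), Krt5 with the same 4 (0.001, 0.001, 0.103 and 0.082), Cd3g with the replicate block (0.11) and Notch3 with library totals only (-0.049). Over the left-out libraries, log2 fold changes ranged from -0.38 to 0.55 for Fos, -0.50 to 0.77 for Krt5, -0.90 to 0.57 for Krt14, -2.13 to 2.82 for Cd3g, -0.24 to 0.47 for Notch3, -0.76 to 3.05 for Cd2, -0.20 to 0.036 for Bpgm, -0.019 to 0.78 for Cspg4, -1.69 to 0.059 for Fabp4, -0.22 to 0.064 for Nras, -0.15 to 0.022 for Rpl4, -0.020 to 0.49 for Rplp0, -0.15 to 0.60 for Sox10, -0.46 to 0.006 for mt-Cytb, -9.55 to 0.14 for Ddx3y and -13.09 to 0.11 for Eif2s3y, the last fitted against 0 counts. The cause was not tested.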

Other observations

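Of the tests of explanations given here, the refit without keratin and epidermal differentiation complex genes was set out before its result was seen, and the other 5 were chosen after. Keratins made in different parts of skin were called in opposite directions. The keratins of suprabasal epidermis (Krt1, Krt2, Krt10, Krt77 and Krt78) summed to 54220 and 37550 CPM in the libraries labelled Ezh2Y646N and to 3596 and 9331 CPM in those labelled NrasQ61K, and 2 of the 5 rose, Krt77 (log2 fold change 3.28, SE 0.51, edgeR's adjusted p = 0.0323) and Krt78 (3.35, SE 0.40, 0.0243). Krt77 lost its call without Ezh2Y646N replicate 1. The basal keratins Krt5, Krt14 and Krt15 summed to 10350 and 15800 against 7715 and 19980 CPM, with 0 of 3 called. Of 20 tested keratins of the hair shaft and inner root sheath 8 fell and 18 had a log2 fold change below -1. The classes were drawn up after these genes were seen, so no enrichment was tested. Their median was -3.14, also with the 1 member at 0 counts in a group set to its floor. Krt75, a keratin of the companion layer, fell by 3.15 on the log2 scale. Keratins together took 6.42% and 5.41% of counts in the libraries labelled Ezh2Y646N and 1.70% and 3.69% in the others. The genes of this paragraph were named after their values were seen, except Krt10.

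The epidermal differentiation complex, a cluster of barrier genes taken here by position (GRCm38 chromosome 3, 90511034 to 93564643, from S100a1 to S100a10), was mixed. Of its 31 tested genes 6 rose and 2 fell, while 16 lay above 0 and 15 below, with a median of 0.21. Flg2 and Hrnr, at log2 fold changes of 4.20 and 4.77, rose, and Tchh, the hair gene trichohyalin, fell by 2.51. Flg2 and Tchh were named after their values were seen. Krt2, likewise, was at 2898 CPM in Ezh2Y646N replicate 1 and at 38.1 in replicate 2, against 6.95 and 18.8 in the libraries labelled NrasQ61K, and did not pass (adjusted p = 0.485). Prx, a gene of myelin sheaths, was at 149 and 42.8 CPM against 14.4 and 18.1 (adjusted p = 0.0632).

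Lists of immune, metabolic and quality genes gave 0 calls in edgeR and voom. Antigen presentation had a median log2 fold change of 0.24 over 22 genes (camera's adjusted p = 0.419), 3 with an unadjusted p under 0.05 and 0 in DESeq2, with H2-T22 at 0.97, Cd74 at -1.32 and H2-Eb1 at -1.15. The list was higher without Ezh2Y646N replicate 1 (0.00493) or NrasQ61K replicate 2 (0.000355) and lower without NrasQ61K replicate 1 (0.0363). Interferon response had a median of -0.08 over 29 genes (0.985), 1 under 0.05 and 0 in DESeq2, with Eif2ak2 at 0.59, Ifih1 at 0.48 and Trim25 at 0.40. Oxidative phosphorylation had a median of 0.03 over 43 genes (0.674), 0 under 0.05 and 0 in DESeq2, with Ndufb3 at 0.56, Atp5g3 at -0.39 and Ndufa9 at 0.34. Ribosomal proteins had a median of 0.09 over 76 genes (0.30) and mitochondrially encoded genes one of -0.14 over 8 (0.762), each with 0 under 0.05 and 0 in DESeq2; Rplp0, Rpl4, mt-Co1 and mt-Cytb were at 0.20, -0.06, -0.33 and -0.21. Ribosomal proteins were higher without NrasQ61K replicate 2 (0.0415). Dissociation stress had a median of -0.25 over 26 genes (0.30), 4 under 0.05 and 1 lower in DESeq2, with Hsp90ab1 at 0.35 and Fos at -0.001, and was lower without NrasQ61K replicate 1 (4.07e-05).

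Among the remaining cell types, skeletal muscle had a median of 0.60 over 15 genes (camera's adjusted p = 0.296), 2 with an unadjusted p under 0.05, 0 calls in edgeR and voom and 1 lower in DESeq2, with Tpm2 at -1.15 and Acta1 at 0.68, and it was higher without Ezh2Y646N replicate 1 (0.0336). Erythroid genes had a median of 1.55 over 7 genes (0.137), 1 under 0.05 and 0 calls in edgeR, DESeq2 and voom, with Bpgm at -0.09. Lymphocyte and mast cell genes (median -0.09), adipocyte genes (-0.62) and sex-linked genes (-0.98) had 4 tested members each, too few for camera with all 4 libraries, with 0, 1 and 0 under 0.05 and 0 calls in edgeR, DESeq2 and voom. With more members tested, the lymphocyte and mast cell list was lower without NrasQ61K replicate 1 (2.28e-05) and without Ezh2Y646N replicate 2 (0.0347). Cd3g and Cd2 were at -0.30 and 0.11, and Lpl and Fabp4 at -0.92 and -0.84. The Y-linked genes Ddx3y and Eif2s3y were at 121 and 69.3 CPM in Ezh2Y646N replicate 1, 130 and 75.5 in NrasQ61K replicate 1, and 88.3 and 52.5 in NrasQ61K replicate 2. In Ezh2Y646N replicate 2 they were at 0.138 and 0 CPM, where the floor of 3 counts is 0.207 CPM.

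The higher values of called epidermal differentiation genes, such as Hrnr, Flg2, Krt77, Lor and Ivl, were weighed against 4 explanations, though the keratinocyte list as a whole was not called (2 members rose, 5 fell, median 0.01). A lower share of melanocytes would raise every other cell type alike. The mean log2 CPM of the fibroblast and endothelial lists instead differed by -3.94 and -2.47 SE of the replicates (n = 2 each). Macrophage, pericyte and keratinocyte lists differed by -2.06, -0.94 and -0.20 SE. Erythroid, Schwann cell and skeletal muscle lists differed by 2.09, 1.41 and 1.21 SE. With 2 libraries per group, differences of this size are not beyond the spread of replicates, so this test does not decide. It was the third form of this test tried, the first having used classes drawn up with the calls in view and the second no measure of spread. A lower share of melanocytes would also lower the pigmentation list's share of counts. That share was 0.607% and 0.599% in the libraries labelled Ezh2Y646N and 0.588% and 0.624% in those labelled NrasQ61K. It was thus not lower, which argues against this explanation as far as these genes track melanocytes. A small fall within this spread is not excluded. A shift of the library totals by the share of counts in keratins and the epidermal differentiation complex is argued against, since their removal from the totals moved other log2 fold changes by 0.049, where the median of the 149 other higher calls was 2.26, while the refit without both, which kept 100% of those calls, moved the median of all other genes by 0 and so decides nothing. A larger share of suprabasal keratinocytes in the sorted cells, which the tdTomato sort would be expected to remove, may account for the higher values. Krt10 was at 20460 CPM in the libraries labelled Ezh2Y646N against 2980 in those labelled NrasQ61K. Of 25 tested markers, drawn up with the called genes in view and sharing 6 genes with the keratinocyte list, 10 were calls. The 15 that were not called, Krt10 among them, had a median log2 fold change of 1.54, with 14 above 0. Some of their values had been seen too. A change of state in keratinocytes could raise the same markers, so these values do not favour a larger share. A change of state in keratinocytes present in both groups, the Ezh2Y646N allele and body site stay open and were not tested, while sex does not separate the groups: Ezh2Y646N replicate 1 held Y-linked RNA, as both NrasQ61K libraries did, with Hrnr at 319 CPM against 4.74 and 12.5, and 113 of the 157 higher calls were kept without Ezh2Y646N replicate 2.

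Of 20 tested keratins in a class drawn up after the values were seen, 8 hair follicle keratins were called lower. This may reflect fewer cells of the hair shaft and inner root sheath in the sorted cells or less hair keratin RNA per cell. The values do not separate these. Hair shaft cells also make keratin-associated proteins, and the 7 tested Krtap genes had a median log2 fold change of -4.06 (-3.99 with 1 gene at 0 counts set to its floor). The Krtap sums were low, 4.54 and 1.17 CPM against 62.1 and 22.9, and 0 of the 7 passed in edgeR, so this test rests on few counts. It also bears on the hair shaft only, not on the inner root sheath keratins of the class. The stage of the hair cycle, the body site and the allele itself stay open and were not tested, and the sort for tdTomato would be expected to remove such cells.

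Ezh2 RNA may follow the proliferating share of each library. Per 100 CPM of the summed proliferation list, which does not hold Ezh2, it was at 2.62 and 2.46 CPM in the libraries labelled Ezh2Y646N and 2.42 and 2.26 in those labelled NrasQ61K. The SD of the log2 ratio over the 4 libraries was 0.087, against 0.54 for Ezh2 itself, and lay at percentile 0.2 among 9995 genes of at least 10 CPM. The ratio was noticed before it was tested, and how much of the RNA came from the conditional allele was not measured here.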
